A study of Mus musculus with 4 samples.

How the data were processed

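Expression was measured on 2-colour Agilent mouse arrays with the RNA of RAW 264.7 cells in Cy5 and a common reference in Cy3, with no dye swap, per the labels. Each group (untreated, and 1, 4 and 6 h with L. bulgaricus) had 1 array of RNA pooled from 3 cultures. Images were read with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes and the file headers. The deposited files give, per spot, intensity values (median pixel brightness of spot and local background, uncorrected), processed signals that the scanner software had background-subtracted and dye-normalized within the array, and a log10 ratio of Cy5 over Cy3. The deposited table of the whole series holds the same log10 ratio, matched to the scanner files by feature number, so its scale, direction and lack of gene centring are known. Further processing by the authors is not given in the sources used here.

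Spot and background median intensities were corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3 and normalized within each array by loess with control and outlier spots at weight 0, with no step between arrays. Mean signals had been planned; the files used here give median signals, which were used. Control spots and spots marked as non-uniform or population outliers (1.55% to 1.84% per array) were left out; no spot was saturated. Replicate spots of a probe were averaged, then the measured probes of a gene. A probe counted as measured when well above background in both channels on both arrays. Probes were named through their accessions, without versions, in a RefSeq gene table of GRCm38.p6: 27655 of 39429 probes matched, for 20971 genes, and 11774 did not. The array was annotated on mm9, so no coordinates are given. Of the measured genes past the rule, 32 of 39 at 1 h, 38 of 47 at 4 h and 86 of 95 at 6 h rested on 1 probe. Mean signal over background was 53.1, 47.2, 41.1 and 36.2 in Cy5 on the untreated, 1 h, 4 h and 6 h arrays.

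The difference of log2 ratios between 2 arrays cancels the reference and a constant dye effect. With 1 array per group no test was made and no p-value is given: a gene counted when the difference was at least 1 in size, or when a gene not well above background in Cy5 on 1 array was at least 2-fold apart from its bound, which is open to dye bias. Bounds compare the normalized Cy5 value of the bright array with the higher of the dim probe's own value and the lowest value of a probe well above background on the dim array, after Aquantile normalization. They take no account of the reference, so a spot dim in both channels of 1 array also counts. Spot error came from 399 probes with 10 spots each. Gene lists were compared with 10000 random lists of the same size matched on mean signal, as a description of these arrays. Named genes were the 10 highest and 10 lowest per time among measured genes with a name other than a clone, accession, Rik, Gm or LOC number and whose probes share a sign, the 3 largest bounds per direction, up to 4 members per fixed list and 20 benchmark genes; the values of some genes that the rule names are left out of the text. The design, 32 gene lists and 15 alternatives were fixed before the data were examined. Another 14 lists and 4 alternatives were chosen after seeing the data, among them the lists of intestinal and other organ markers. The alternatives changed the background correction, the normalization within and between arrays, the source of the values (processed signals, the deposited ratios, or Cy5 without the reference), the filters, the choice of probe and the rule of size.

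The steps were tested on simulated data: a second array was made from the untreated array with spot noise and 200 genes changed by known folds. For the 1 h comparison, with 10485 genes measured, 72.0% of genes changed 3-fold, 76.0% of those changed 4-fold and 8.0% of those changed 2-fold were called, and 0 unchanged genes. For the 4 h comparison, with 10490 genes, the shares were 72.0%, 76.0% and 6.0%, and for the 6 h comparison, with 10487 genes, 64.0%, 82.0% and 0%. The offset shrinks differences: in the 1 h simulation genes raised 4-fold (log2 2) had a median of 1.63. The simulation has spot noise alone. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.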

Results

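RAW 264.7 is a mouse macrophage-like cell line transformed by Abelson leukaemia virus, and Lactobacillus bulgaricus is a lactic acid bacterium of fermented milk. The design asked how gene expression in these cells moved over time with the bacteria at a multiplicity of infection of 10. There were 4 two-colour arrays, 1 each for untreated cells and for cells after 1, 4 and 6 h, and each array held RNA pooled in equal amounts from 3 cultures. The sample was labelled with Cy5 and set against a Cy3 common reference, which the labels describe as RNA pooled from all the groups. All 4 arrays lay on 1 slide, and the position on the slide followed the time, so position and time cannot be told apart. Cy5 was well above background at 51.4% of spots on the untreated array and at 51.8%, 51.0% and 49.5% on the 1 h, 4 h and 6 h arrays. With 1 array per group there was no replicate array and no test, and the number of arrays limits the precision. A gene counted as higher or lower when its log2 ratio differed by at least 1 from that of the untreated array. Replicate spots gave an SD of 0.12, 0.13 and 0.13 for a log2 difference at 1, 4 and 6 h, which covers spot error and not the spread between cultures.

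After 1 h the immediate early genes, which answer a stimulus before new protein is made, stood above untreated cells. The nuclear receptor genes Nr4a1 (log2 difference 1.76) and Nr4a2 (1.76) were the highest of them, and Ier2 (1.27), Klf2 (1.24) and Fosb (1.13) also rose; the last 3 were chosen after their values were seen. In this list 5 of 22 measured members were higher, 0 were lower, 21 lay above 0, and the median of 0.49 had a percentile of 100 among 10000 random lists matched on signal. Fos, a benchmark gene, was the 1 member below 0, at -0.02. The MAP kinase phosphatases and feedback regulators had a median of 0.24 (percentile 99.98) with 0 of 10 members past the rule; Dusp2, a nuclear phosphatase, stood at 0.83. Cd83, an activation marker of antigen-presenting cells, stood at 0.92, Egr2 at 0.94 and the cytokine gene Osm at 0.71, none past the rule. Chac1, an enzyme that degrades glutathione, rose by 1.32. For Klf2 the normalized Cy5 signal alone moved by 0.35 and the reference by -0.90. The chemokine list had a median of 0.18 (percentile 99.6) with 0 of 11 members past the rule, and the proinflammatory cytokines one of 0.16 (percentile 97.1) with 0 of 6.

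The largest differences at 1 h were in transcripts known from the intestine. Reg3b (log2 difference 4.18) and Reg3g (3.02), antimicrobial lectins, led the ranking, followed among these transcripts by the pentraxin gene Mptx1 (2.78), the alpha-defensin Defa38 (1.87), the mucus protein gene Fcgbp (1.79), Defa29 (1.71) and the angiogenin Ang4 (1.70), whose Cy5 signal alone moved by 0.39 while the reference moved by -1.31. The alpha-defensins are near-identical copies, so signals of single members are uncertain. Of the 34 genes higher at 1 h, 19 were alpha-defensins or members of intestinal, smooth muscle or exocrine gland lists written after the data were seen. Such lists are not complete, so the rest may still hold intestinal genes. These transcripts were also bright in the reference. The processed Cy5 signal of Reg3b was 76.3 on the untreated array and 1908, 840 and 554 on the 1 h, 4 h and 6 h arrays, while its Cy3 signal was 3361, 1631, 1788 and 1675. Fabp2, an enterocyte fatty acid carrier chosen, like Vil1, after its values were seen, had Cy3 signals of 4294 to 4637 and Cy5 signals of 698 to 1153.

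**Figure D1:**
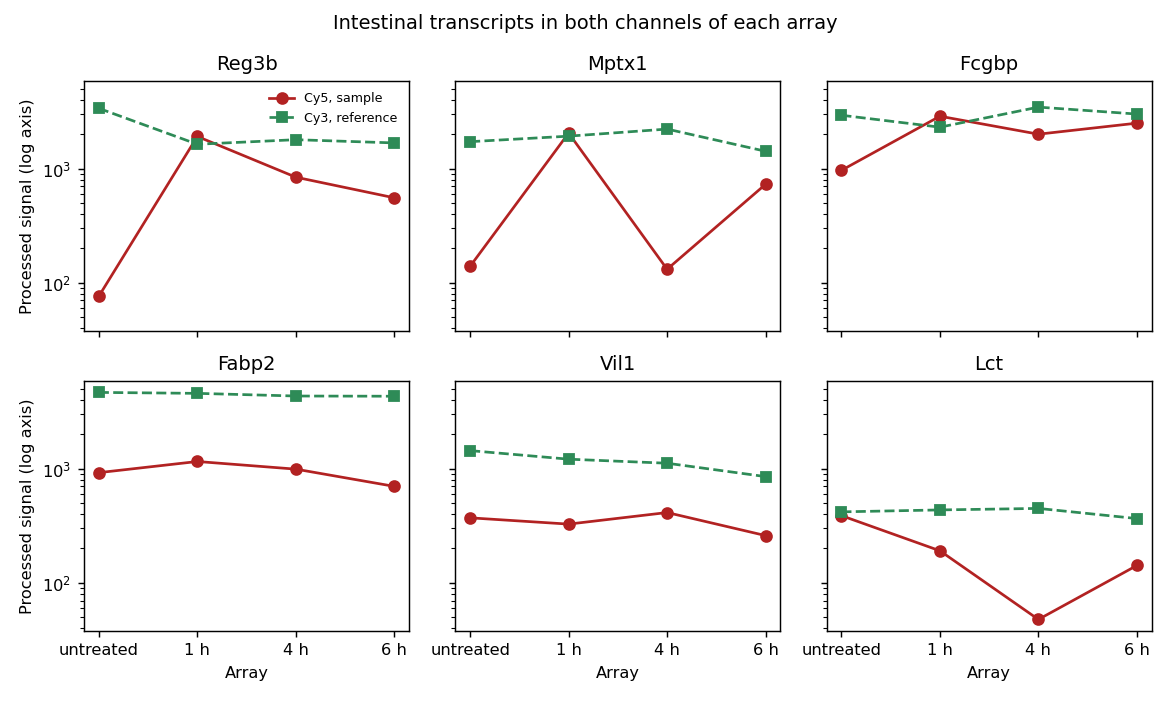
Processed signal (log axis) of 6 intestinal transcripts on the 4 arrays, Cy5 being the sample and Cy3 the common reference; each point is 1 array. The Cy5 signal of Mptx1 was 139.5 on the untreated array, 2042 at 1 h, 131 at 4 h and 728 at 6 h, while Fabp2 and Vil1 stayed below the reference on every array.

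Genes lower at 1 h numbered 9. The 5 that were measured on both arrays were Dad1 (-1.43), a subunit of the oligosaccharyltransferase, Hsd17b7 (-1.38), Anapc7 (-1.20), Lsm7 (-1.12) and Tnni2 (-1.07); Hsd17b7 was named after its value was seen, since its probes differed in sign. In all 5 the Cy5 signal alone was higher at 1 h, by 0.09 to 0.86, and the reference signal was higher by 1.16 to 2.24, so none fell in Cy5. The other 4 were bounds in Cy5 against an array on which it was not well above background. Prdx4, Twsg1 and Tex261 led them, at least 7.79-fold, 4.49-fold and 3.37-fold lower in Cy5 (log2 -2.96, -2.17 and -1.75). The reference was dimmer on the same array by 2.91, 1.95 and 1.90, and by at least 1 in all 4. These bounds thus hold for Cy5 and not for the ratio. Bud13, listed at 2.74, had an outlying local background at 1 h and stood at -0.19 from the scanner's processed signals. Of the 34 higher genes, 20 also passed the rule in Cy5 alone and 31 had the same sign. Between the same arrays the reference channel, which holds the same RNA, differed by at least 1 in 1.16% of genes, against 0.376% of genes for the ratio. These are unlike measures, since changes shared by both channels of a spot count in a single channel and cancel in the ratio. The SD of the differences was 0.29 in the reference and 0.19 in the ratio, so the reference share does not give the error of the ratio. Among 10369 genes measured at 1 h, 34 were higher and 5 lower than in untreated cells, beside the 4 bounds; with bounds the counts were 34 and 9, and in Agilent's processed signals in 91 and 68.

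After 4 h Ier3, an early response gene of stressed cells, stood at 2.12, behind Reg3b and Reg3g in the ranking, and the metal-binding metallothionein Mt2 at 1.65. Cxcl2, a neutrophil-attracting chemokine, rose by 1.02, while Tnf stood at 0.94, Hmox1 at 0.92, Mt1 at 0.87 and Ccl4 at 0.80. The immediate early list had a median of -0.09 (percentile 2.43) with 1 of 23 members higher and 1 lower. The chemokine list had a median of 0.23 (percentile 99.9) with 1 of 11 members higher, the proinflammatory cytokines 0.23 (percentile 99.02) with 0 of 6 past the rule, and the oxidative stress response 0.28 (percentile 100) with 20 of 21 members above 0 and 1 past the rule.

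Several of the transcripts lowest at 4 h also fell in Cy5 alone, and others did not. Id2 (-2.03) and Id3 (-1.32), inhibitors of basic helix-loop-helix factors, Trib1 (-1.64), an adaptor that promotes degradation of C/EBP proteins, Cx3cr1 (-1.36), the fractalkine receptor, and Mir17hg (-1.31), the host transcript of a microRNA cluster, all passed the rule, and each fell by over 1 in Cy5 alone. Cxcr3 (-1.30) and Cyp51 (-1.09) passed on the ratio, but their Cy5 signal alone moved by 0.18 and -0.21 while the reference moved by 1.47 and 0.89. Rtp4, an interferon-induced gene, fell by 1.23. Among interferon-stimulated genes the median was -0.32 (percentile 0) with 24 of 29 members below 0 and 0 past the rule, for example Oas2 at -0.68 and Ifi204 at -0.61. Cholesterol and fatty acid synthesis had a median of -0.20 (percentile 0), with all 24 measured members below 0 and 2 past the rule. The unfolded protein response had a median of -0.36 (percentile 0) with 0 of 18 past the rule, and Herpud1, an endoplasmic reticulum degradation factor, stood at -0.95. The cell cycle list had a median of -0.10 (percentile 0.15), with 26 of 33 members below 0 and 0 past the rule. In the processed Cy5 signal alone its median was 0.0017 (percentile 1.825), where the median of all genes was 0.0876.

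Intestinal transcripts also led the 4 h ranking, with Reg3b at 2.98, Reg3g at 2.38, Defa40 at 2.03, Defa3 at 1.87, Defa38 at 1.84, Defa2 at 1.59, and the smooth muscle myosin light chain Myl9 at 1.53. Lct, the intestinal lactase, fell by 1.71. Markers of fibroblasts, endothelium and epithelium had a median of 0.30, 0.36 and 0.27 at 1, 4 and 6 h (percentiles 100, 100 and 99.9), with 0 of 9 past the rule at each time; Dcn stood at 0.17, 0.77 and 0.93 and Krt18 at 0.64, 0.46 and 0.87. At 4 h, 25 genes were higher and 22 lower of 10339 measured, and 3 bounds made 25 lower genes. Of the higher genes 16 were alpha-defensins or members of the intestinal, smooth muscle or gland lists, which leaves 9. The lists are not complete, so these 9 may still hold intestinal genes. Of the measured genes past the rule, 16 of 25 higher and 9 of 22 lower genes also passed in Cy5 alone, and in 10 of 47 the reference moved by at least 1. The lower bounds Twsg1 (at least 5.04-fold) and Tmlhe (at least 3.23-fold) were at log2 -2.33 and -1.69 in Cy5. Their reference was dimmer by 1.88 and 1.83 on the same array, so both hold for Cy5 and not for the ratio. The reference of Fabp1 (at least 2.49-fold lower) was dimmer by 0.23. Hsd17b7 (-1.73) and Dad1 (-1.51) were lower as at 1 h, with the reference moved by 2.05 and 2.19.

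After 6 h Cxcl2 reached 1.58, Csf3, the granulocyte colony-stimulating factor, 1.27, Cxcl10 1.11 and Ptgs2, the inducible cyclooxygenase, 1.05, while Tnf stood at -0.24 and Ccl4 at 0.02. Ier3 (1.65), Mt2 (1.61), Hmox1 (1.37), the heme oxygenase, and Gadd45b (1.29), a stress sensor, were higher. The oxidative stress list had a median of 0.33 (percentile 100), with 19 of 21 members above 0 and 2 past the rule, the chemokine list one of 0.17 (percentile 98.7) with 2 of 12 members higher, and the proinflammatory cytokines one of -0.03 (percentile 46.8) with 1 of 6 higher. The autophagy list had a median of 0.15 (percentile 98.4) with 0 of 17 past the rule; Sqstm1, a cargo receptor for autophagy, stood at 0.92.

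Leaving aside genes known by a Gm or Rik number, genes lower at 6 h were led by Mir17hg (-2.56), Id2 (-2.15), Trib1 (-2.00), Cxcr3 (-1.87), Hsd17b7 (-1.83), Chac1 (-1.73), Dad1 (-1.69), Cx3cr1 (-1.69), Id3 (-1.65) and Trim25 (-1.57), a ubiquitin ligase of the antiviral response. The reference had moved by 1.49 for Cxcr3, by 2.26 for Hsd17b7, by 2.30 for Dad1, by 0.96 for Chac1 and by 0.63 for Trim25, whose Cy5 signals alone moved by -0.38, 0.43, 0.62, -0.77 and -0.94. Fos fell by 1.26 and Nfkbid, an atypical inhibitor of NF-kB, fell by 1.18. Plaur, listed at -1.08, had a Cy5 signal that moved by 0.24 while its reference moved by 1.32. Cholesterol and fatty acid synthesis kept a median of -0.21 (percentile 0.28), with 23 of 24 members below 0 and 3 past the rule. The unfolded protein response stood at -0.50 (percentile 0) with 1 of 18 lower, interferon-stimulated genes at -0.30 (percentile 0) with 1 of 29 lower, and the cell cycle list at -0.19 (percentile 0.14), with 27 of 32 members below 0 and 0 past the rule; Mki67 stood at -0.68. Pattern recognition receptors had a median of -0.17 (percentile 0.79) with 0 of 23 past the rule, and markers of osteoclasts and dendritic cells one of -0.24 (percentile 1.28) with 0 of 8. The same markers stood at -0.06 (percentile 0.56) at 1 h, and at 0.04 in the processed Cy5 signal alone.

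At the top of the 6 h ranking stood Reg3b (2.46), Sycn (2.38), a zymogen granule protein, Saa1 (2.35), an acute phase protein, the linker histone H1f2 (2.23), Tspan1 (2.19), the kallikreins Klk1b5 (1.93) and Klk1 (1.89), Ly6c1 (1.92), Ly6a (1.88) and Lypd8 (1.82), a colonic epithelial protein whose Cy5 signal alone moved by 0.17 while its reference moved by -1.65. Of 10311 measured genes 47 were higher and 48 lower at 6 h, and with bounds 54 were higher and 61 lower. Among the 54, 14 were alpha-defensins or members of the intestinal, smooth muscle or gland lists. Lypd8 is not on these lists, so the other higher genes still hold intestinal transcripts. Of the 115, 20 were bounds, in 14 of which the reference was also dimmer by at least 1. The bounds included Sec61a1 (at least 13.1-fold lower), Pi4k2b (at least 11.2-fold lower) and Phax (at least 3.76-fold higher) in Cy5, or log2 -3.71, -3.48 and 1.91. Their reference was dimmer by 3.07, 3.24 and 1.95 on the dim array, so these bounds do not hold for the ratio. In Wfdc2 (at least 2.81-fold higher) and H2bc23 (at least 2.42-fold higher) the reference moved by under 1. Of the measured genes, 37 of 47 higher and 19 of 48 lower ones also passed the rule in Cy5 alone. Without genes whose reference moved by at least 1, the counts were 50 higher and 37 lower. The reference channel differed by at least 1 in 2.56% of genes between these arrays, as a single channel and not a ratio.

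**Figure D2:**
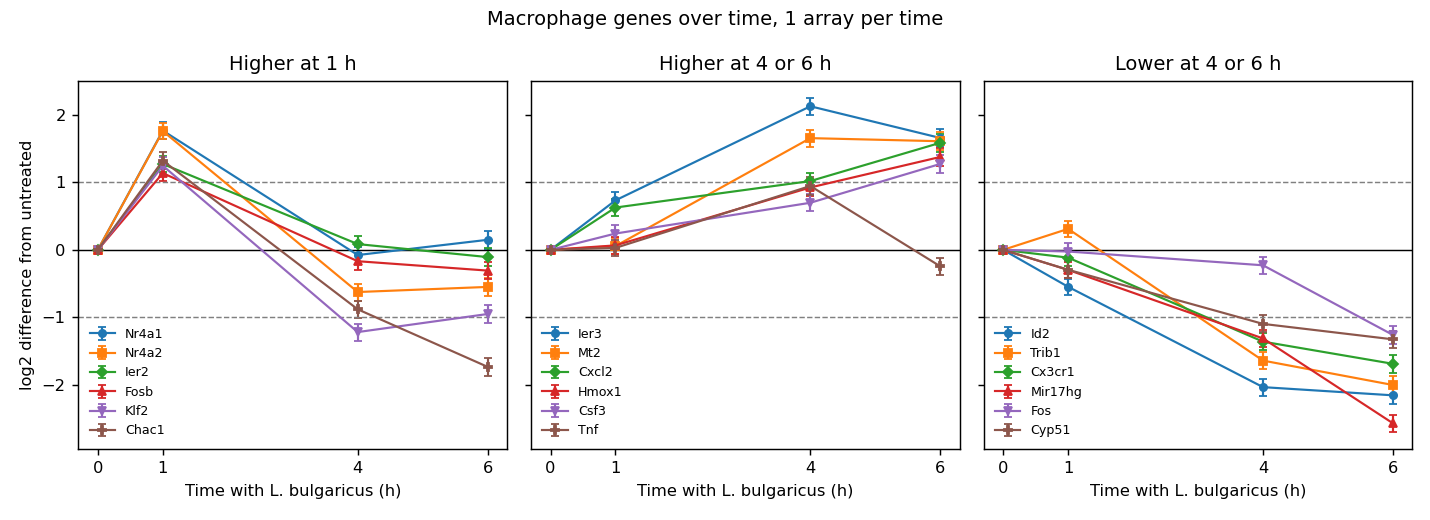
Log2 difference of the Cy5/Cy3 ratio from untreated cells (y axis) against hours with the bacteria (x axis) for 18 genes, 1 array per time, with error bars of 1 SD from replicate spots and dashed lines at the rule of size. Tnf stayed under the rule with 0.94 at 4 h, and Cyp51 moved by -0.26 in Cy5 alone at 6 h. Nr4a1 and Nr4a2 peaked at 1.76 at 1 h, Ier3 at 2.12 at 4 h, and Id2 reached -2.15 at 6 h.

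Successive times were compared in the same way. From 1 h to 4 h, 4 genes were higher and 40 lower of 10537 measured, and 5 and 41 with bounds. From 4 h to 6 h, 20 were higher and 15 lower of 10505 measured, and 33 and 19 with 17 bounds, in 12 of which the reference was also dimmer by at least 1. Of 10115 genes measured in all 3 comparisons with untreated cells, 128 passed the rule at 1 or more times. Higher at 1 h alone were 10, higher at 6 h alone 28 and lower at 6 h alone 33, whereas 4 were higher and 3 lower at all 3 times. The 3 lower ones, named after their values were seen, were Dad1, Hsd17b7 and Tnni2, and in none of them did Cy5 alone fall by the rule of size at any time, while the reference moved by 1.07 to 2.30. Genes higher at both 1 and 4 h numbered 13, at both 1 and 6 h 12 and at both 4 and 6 h 10, against 0.08, 0.15 and 0.11 for independent lists; lower genes shared between times numbered 4, 3 and 14, against 0.01, 0.02 and 0.10. Simulated unchanged groups sharing the untreated array shared 0 genes. That was bound to follow, since their spot noise gave differences an SD of 0.12 to 0.13 against a rule of 1. This 0 thus lends the overlaps no weight. Differences in the reference channel, with the same RNA, had an SD of 0.29 to 0.40. Reference values here and below are of a single channel, where changes shared by both channels do not cancel, so they do not measure the error of the ratio. The covariance of the differences was 0.02, 0.02 and 0.05 for the same pairs of times, against 0.01 in that simulation, and 0.07, 0.07 and 0.09 in the reference channel. In the reference channel itself 30, 32 and 44 genes were higher and 39, 33 and 47 lower at both times of a pair, so the untreated array's reference contributed to shared lower genes such as Dad1, and its part in the other counts was not split off.

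The benchmark genes of macrophage activation gave mixed values. Il1b, Il6, Arg1 and Mrc1 were not well above background on any array, Egr1 reached it in Cy5 at 1 h alone and never in the reference, and Il10 lacked it in the reference on the untreated array. Il12b had no probe with its symbol here, and the Actb probe was left out as an outlier spot on the 3 treated arrays. Nfkbia stood at -0.14, 0.53 and 0.07 at 1, 4 and 6 h, Tnfaip3 at 0.39, 0.65 and 0.89 with a reference that moved by -1.68, -0.44 and 0.63, Socs3 at 0.14, 0.16 and -0.20, and Tlr2 at -0.01, 0.43 and -0.62. Nos2, the inducible nitric oxide synthase, stood at -0.67, -0.93 and -0.61, but its Cy5 signal alone moved by 0.15, -0.29 and 0.18 and its reference by 0.82, 0.64 and 0.78. Ccl3 stood at -0.05, 0.02 and 0.13, with a Cy5 signal of 13417 at 6 h against 349 in untreated cells and a reference of 13660 against 444. Gapdh stood at -0.90, -0.98 and -0.64 but at 0.02, -0.19 and 0.08 in Cy5 alone, with a reference that moved by 0.92, 0.79 and 0.72.

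Glycolysis and hypoxia genes had medians of 0.13, -0.14 and -0.00 at 1, 4 and 6 h (percentiles 99.96, 0.14 and 59.4), and ribosomal proteins -0.08, -0.08 and 0.14 (0.07, 4.79 and 98.1), though without loess the latter stood at 0.95 at 1 h and -0.02 at 6 h. Without loess the median of all genes at 1 h was 0.86, and the ribosomal percentiles were 1.60 at 1 h and 96.1 at 6 h. LXR targets and lipid handling had medians of 0.03, 0.20 and 0.10 (22.6, 99.8 and 92.1), and alternative activation markers 0.16, -0.12 and -0.20 (98.5, 4.40 and 4.30), the first of these being -0.01 in processed signals. Housekeeping genes had medians of 0.02, -0.13 and -0.11 (38.5, 1.48 and 16.1), with 9 of 12 below 0 at 4 h, heat shock genes 0.09, -0.14 and -0.11 (96.2, 1.21 and 20.1) and B cell markers -0.12, -0.05 and 0.01 (2.46, 29.4 and 54.1), the last over 3 genes and at 0.12 at 1 h without loess. The percentile of that 0.12 was 0.35. NF-kB components (0.08, 0.07 and 0.03), anti-inflammatory and SOCS genes (0.08, 0.11 and 0.03), inflammatory effector enzymes (0.03, -0.05 and -0.05), antigen presentation (0.10, -0.00 and -0.02), apoptosis regulators (0.06, -0.07 and 0.07), the mitochondrial respiratory chain (-0.02, 0.00 and 0.03), phagocytosis (0.07, 0.04 and 0.02), lysosome (0.03, 0.06 and -0.04), chromatin modifiers (0.06, 0.00 and -0.11), macrophage identity (0.03, 0.07 and -0.12) and T cell markers (0.08, 0.08 and 0.05) had percentiles of 5.90 to 96.8 at the 3 times. In the list of neutrophil and mast cell markers 2 genes were measured, too few for a median.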

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

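All tests in this part were chosen after the results were seen. Chac1 and Klf2 passed the rule of size in opposite directions at different times: Chac1 was at 1.32 at 1 h and -1.73 at 6 h, and Klf2 at 1.24 at 1 h and -1.22 at 4 h; the difference between times was not tested, since each time had 1 array. In Cy5 alone Chac1 moved by -0.77 at 6 h, under the rule of size, while its reference moved by 0.96. Klf2 at 4 h stood at -0.83 when arrays were scaled to each other, and at 1 h at 0.36 in the processed Cy5 signal alone. Targets without a gene symbol, which no comparison used, were higher than in untreated cells in 7 cases at 1 h, 12 at 4 h and 24 at 6 h, and lower in 1, 4 and 19.

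Intestinal transcripts were bright in both channels, and Paneth cell genes were higher after treatment, with a median of 1.35, 1.32 and 0.71 at 1, 4 and 6 h (12 genes). At 1 and 4 h part of this lay in the reference, whose median over these genes moved by -0.48 and -0.53. In Cy5 alone the medians were then 0.83 and 0.80, with 5 and 4 of the 12 past the rule of size. At 6 h the reference median moved by -0.40, but the Cy5 median of 0.88 was not below that of the ratio. There 6 of the 12 passed in Cy5 alone and 5 in the ratio. Of 67 genes on 4 lists of enterocyte, goblet, Paneth and smooth muscle genes, 97.0% were well above background in Cy5 on the untreated array, against 24.3% of 74 genes on 5 lists of liver, muscle, nerve, kidney and lung or skin; 1 of the 73 members of the intestinal lists is also on the macrophage list. An equal pool of the 4 samples should give a mean Cy5/Cy3 ratio near 1, but the median over 52 intestinal epithelial genes was -0.66 on the log2 scale, percentile 0 among random lists, so intestinal RNA beyond that pool in the reference is a candidate source. One intestinal RNA of fixed make-up in varying amounts would move such genes one way in each comparison, and of 27 moves past the rule in both ratio and Cy5, over 49 genes measured throughout, 3 ran against the majority (Lct at 4 h, Fabp6 from 1 h to 4 h and Defa2 from 4 h to 6 h). Fabp1 was outside these 49, since its Cy5 signal was not well above background at 4 and 6 h. As bounds in Cy5 it was lower there by at least 2.49-fold and 2.15-fold, also against the majority. An RNA of 1 make-up predicts 0 moves against the majority, so these 3 and Fabp1 run against it. The majority was 5 to 1 in the comparison of Lct, 3 to 1 in that of Fabp6 and 2 to 1 in that of Defa2. Each move rests on 1 array per group, with no measure of the error between arrays, so these moves do not decide. The percentile of 99.985 among matched random lists does not decide, since those lists held a median of 0 and at most 12 moves past the rule. Such an RNA therefore stays open. A test of Cy3 light read in Cy5 did not decide: the median Cy5 share of intestinal spots was 3.37 to 25.9 times that of the single lowest bright Cy3 spot of the same array, but 1.495 to 2.17 times that reached by the lowest 0.1% of such spots, and a single spot can be defective in Cy5, so a partial leak stays open. A further test, added after that outcome, looked within each array, where light alone would give intestinal spots 1 common Cy5 share; the interquartile range of their log2 Cy5/Cy3 was 8.96 to 16.2 times that of replicate spots on the 4 arrays, which argues against such light as the whole Cy5 signal. The intestinal Cy5 signal on the untreated array was not a response to the bacteria, since those cells had none. For the rise after treatment, a response of the cells and intestinal RNA in the samples cannot be told apart with 1 array per group.

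The 9 genes lower at 1 h all had a reference signal that moved by at least 1 or an outlying local background, as did 13.02% of all measured genes; among the 34 genes higher at 1 h the reference of 5 moved and 6 had an outlying background. Of the 5 measured on both arrays, 0 fell by the rule of size in Cy5 alone, with a median of 0.48. This does not decide on a response of the cells, since a spot dim in both channels on the untreated array would also raise Cy5 alone. Defects of spots or background, not all on the same array, may account for the 9. The Cy3 signal of Dad1 was 2486 on the untreated array and 11248, 12284 and 14081 at 1, 4 and 6 h, whereas that of Prdx4 was 1135, 9.1, 366 and 7711.

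Histone genes rose at 6 h in 8 cases, among them H1f2 (2.23), H2aw (1.77) and H2bc4 (1.71), named after their values were seen, although the median over 27 measured histone genes was -0.03. The reference of 0 of the 8 moved by at least 1, and their Cy5 signal alone rose by 0.97 to 2.47, which argues against spot defects. More cells in S phase is argued against by the cell cycle list, whose median had a percentile of 0.14 among random lists. Histone genes are close paralogs, and with 1 array per group a response of the cells stays open as untested, as does signal shared between paralogs.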

How the results depend on the processing

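Leaving out spots with an outlying background, bounds, intestinal genes or genes with a moved reference was chosen after seeing the data; the other alternatives were fixed before. Counts of genes higher and lower than in untreated cells are given for 1, 4 and 6 h, then for 4 h against 1 h and 6 h against 4 h, beside 34 and 9, 25 and 25, 54 and 61, 5 and 41, and 33 and 19 as reported. All 10 counts stayed within 1.5 times the reported ones with normexp offset 16, the brightest probe per gene, Cy5 above background on 1 of 2 arrays, outlier spots kept, and background outliers left out. With Aquantile normalization the counts were identical to those reported. That was bound to follow, since this step leaves the log2 ratios as they are and the bounds already use it.

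Agilent's processed signals, median centred, gave 91 and 68, 102 and 146, 161 and 381, 74 and 122, and 81 and 102. The deposited ratios of the series gave 117 and 46, 146 and 101, 236 and 208, 83 and 116, and 91 and 77. Cy5 alone, from processed signals without the reference, gave 127 and 129, 232 and 265, 484 and 506, 96 and 123, and 209 and 137. These 3 settings add no offset but also change other steps, and the cause of their counts was not tested. With the offset alone lowered to 16, the counts were 38 and 10, 31 and 37, and 72 and 83 at 1, 4 and 6 h. With a rule of 1.5-fold the counts were 137 and 59, 139 and 156, 224 and 378, 49 and 181, and 94 and 139, and with 3-fold 14 and 3, 8 and 6, 18 and 19, 1 and 12, and 12 and 4, as a looser or stricter rule must give more or fewer genes.

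Median centring without loess gave 3030 higher and 4 lower genes at 1 h, 123 lower at 6 h, 2 higher and 3178 lower from 1 h to 4 h, and 33 lower from 4 h to 6 h; it moved the median of all genes to 0.86 at 1 h, -0.15 at 6 h and -0.83 from 1 h to 4 h. Scaling between arrays gave 64 higher and 20 lower genes at 1 h, 46 higher at 4 h, 23 higher and 75 lower from 1 h to 4 h, and 7 lower from 4 h to 6 h. Without background subtraction 15 genes were lower at 1 h, 46 higher at 4 h, 92 higher at 6 h and 11 higher from 1 h to 4 h. For the counts under these 3 settings the cause was not tested. Without a filter on background, which also drops the bounds, 3 genes were lower at 1 h and 40 at 6 h. Without bounds 5 were lower at 1 h and 20 higher from 4 h to 6 h, and 20 were higher from 4 h to 6 h among genes above background on all 4 arrays. Without the intestinal genes counted here, whose lists are not complete, 15 were higher at 1 h and 9 at 4 h. Without genes whose reference moved, 0 were lower at 1 h, 15 at 4 h and 37 at 6 h.

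The share of higher genes was 79.1% at 1 h, 50% at 4 h, 47.0% at 6 h, 10.9% from 1 h to 4 h and 63.5% from 4 h to 6 h. It became 57.2%, 41.1%, 29.7%, 37.8% and 44.3% in processed signals, where the median of all genes was -0.12 at 4 h and -0.20 at 6 h. It became 99.9% at 1 h, 28.1% at 6 h, 0.1% and 48.4% from 1 h to 4 h and 4 h to 6 h without loess, and 63.9% at 4 h, 23.5% and 78.1% with scaling. In Cy5 alone, where the median of all genes was 0.12 at 6 h, it was 49.6% at 1 h and 43.8% from 1 h to 4 h.

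Of 101 single-gene values past the rule that were followed across settings, 101 passed it with offset 16, 97 in processed signals, 97 without background subtraction, 97 in the deposited ratios, 97 with scaling, 94 without loess, 100 with the brightest probe and 70 in Cy5 alone. With Aquantile normalization all 101 had to pass, since it leaves the log2 ratios as they are. Of 91 with a value without background outliers, 88 did. Over all settings 13 of the 101 single-gene values past the rule changed sign, some in several settings (20 cases), and 8 list medians did (9 cases). Sign changes of single-gene values under the rule were not counted. In Cy5 alone Anapc7 stood at 0.35 at 1 h and 0.63 at 4 h, Cxcr3 at 0.12 at 4 h, Dad1 at 0.65, 0.82 and 0.88 at 1, 4 and 6 h, Lsm7 at 0.15 at 1 h, Plaur at 0.28 at 6 h, Tnni2 at 0.0419, 0.0603 and 0.28 at 1, 4 and 6 h, and Hsd17b7 at 0.11 at 1 h. Bud13 at 1 h stood at -0.19 in processed signals, -0.0996 without background subtraction and -0.0897 in the deposited ratios. Hsd17b7 at 1 h stood at 0.0400, 0.15 and 0.14 in the same settings and at 0.14 without background outliers. Lsm7 at 1 h stood at 0.0391 without loess, where the median of all genes was 0.86. The cause was not tested for any of these genes.

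Among list medians, alternative activation markers at 1 h stood at -0.0092 in processed signals. Without loess, ribosomal proteins stood at 0.95 at 1 h and -0.0221 at 6 h, and at 1 h B cell markers stood at 0.12, markers of osteoclasts and dendritic cells at 0.72 and histone genes at 0.75. The median of all genes at 1 h was 0.86 in that setting. Ribosomal proteins, B cell markers and histone genes kept low percentiles at 1 h, of 1.60, 0.35 and 0.70. Markers of osteoclasts and dendritic cells had 32.15, and ribosomal proteins at 6 h had 96.1. In Cy5 alone the cell cycle list stood at 0.0017 at 4 h (percentile 1.825), where the median of all genes was 0.0876. At 1 h markers of osteoclasts and dendritic cells stood at 0.0365 and enterocyte genes at -0.0037 in Cy5 alone (percentiles 47.7 and 24.25). The cause was not tested for the values in Cy5 alone or in processed signals. Of 51 list medians outside the central range of random lists, 35 were outside it in Cy5 alone and 42 to 48 in the other settings. That leaves aside Aquantile normalization, which cannot change these medians and gave 51. Mean signal over background fell from 53.1 on the untreated array to 36.2 at 6 h in Cy5, which limits calls of dim genes.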

Other observations

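The lists and the genes named here were chosen after the data were seen. Id genes and targets of BMP or TGF-beta signalling had a median of 0.04, -0.46 and -0.45 at 1, 4 and 6 h (percentiles 36.1, 0 and 0.01), with 3 of 8 members lower at 4 h (Id1, Id2 and Id3) and 2 at 6 h; Skil stood at -0.47 at 4 h. Genes of the amino acid response had medians of 0.07, -0.08 and -0.07 (percentiles 86.0, 4.37 and 23.2). At 6 h 4 of 21 were lower, namely Chac1 (-1.73), Mat2a (-1.57), the methionine adenosyltransferase, Stc2 (-1.52) and Slc38a2 (-1.21), an amino acid transporter, while Atf3 stood at 0.94 and Ddit3 at 0.89, both under the rule of size. The Stc2 reference moved by 0.97, and that of Chac1 by 0.96 at 6 h. The p53 target list had medians of 0.11, -0.05 and 0.08 (percentiles 92.1 and 14.3 at 1 and 4 h), with 0 of 16 past the rule.

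Goblet cell genes had medians of 0.74, 0.41 and 0.72 (percentile 100 at each time), enterocyte genes 0.27, 0.19 and 0.06 (percentiles 100, 100 and 84.8, the first median being -0.0037 in the processed Cy5 signal alone), visceral smooth muscle genes 0.46, 0.90 and 0.60 (percentile 100 at each time) and exocrine pancreas and salivary gland genes 0.81, 0.21 and 1.91 (percentiles 100, 97.7 and 100), the last over 4 or 5 genes. Hepatocyte genes had medians of 0.01, -0.03 and -0.04 and neuronal genes -0.01, -0.01 and -0.06, each over 4 genes; 1 gene or none was measured on the muscle, kidney and lung or skin lists. The ratio was at or below -1 on all 4 arrays in 7 of 10162 genes and at or above 1 in 0. Fabp1 had a Cy5 signal of 235 on the untreated array and 89.9, 6.0 and 11.5 at 1, 4 and 6 h.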
